A study of Mus musculus with 3 samples.

How the data were processed

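Small RNAs were sequenced in 3 libraries, 1 per group, so no difference between groups has a replicate check. The first was an RNA immunoprecipitate with an antibody against MIWI2 (PIWIL4), a PIWI-family protein that binds PIWI-interacting RNAs (piRNAs), from MEL cells, a line of Friend virus-transformed mouse erythroblasts. The second was the same kind of immunoprecipitate from unfractionated splenocytes of 10-week-old C57Bl6/J mice. The third, from adult testis of the same strain and age, was no immunoprecipitate: per the labels' protocols, total RNA was separated on an 18% polyacrylamide gel and the band near 29 nt was cut out. An input library or a control immunoprecipitate was not analysed here.

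The deposited files hold positions rather than values, and list mapped reads, with the chromosome, start and end of a read on each line and copies of a read on repeated lines. They carry no strand, sequence, read name, count or score, and nothing was normalised by the authors as far as the values show. Reads were mapped with Bowtie 0.12.7, per the submitters' processing notes. The mapping options, the adapter trimming, the treatment of reads with several matches and the genome build are not given in the sources used here. End minus start was taken as the read length. The longest lengths were 36 nt in the MEL and testis libraries and 40 nt in the spleen library, so the spleen library differed from the others in its longest reads, and the shortest reads were 7, 11 and 9 nt in the MEL, spleen and testis libraries. Chromosome names ending in _random and reads on chromosome 7 as far as position 152523579, beyond the last gene of that chromosome in GRCm38 at 145324059, excluded GRCm38 as the build. The naming is that of the mm9 assembly, which was not used here to check it. Gene annotation of GRCm38 was therefore not joined to these positions and no gene is named. Coordinates are those of the files, counted from 1.

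From the lines, reads were counted per length, per interval (a distinct pair of start and end), per left end and per 10 kb window tiled from the start of each chromosome, and scaled to a library total of 1000000 reads (RPM). A cluster was 1 or more 10 kb windows with at least 100 RPM and at least 20 distinct left ends, joined when at most 1 window lay between them. The share of reads in clusters was set beside the share that their length took of the 119251 windows with a read in any library. Left ends shared between libraries were set beside the mean of 100 random shifts of each end by 100 to 1000 nt in either direction. Windows were called higher in a library when it had at least 100 RPM there and at least 4-fold more than the other library, with a library under 3 reads set at 3 reads. Correlations across windows used log2(RPM + 1) over windows with at least 10 RPM in either library. Windows low in both libraries were thus left out, which can lower a correlation. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

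The libraries held 823452 (MEL), 692011 (spleen) and 1143785 (testis) reads, so 3 reads corresponded to 3.64, 4.34 and 2.62 RPM. Shares are given with exact Clopper-Pearson 95% intervals and RPM with exact Poisson 95% intervals. Reads carry no molecular identifiers, so copies made by PCR count as separate reads, and intervals cover counting error only. Reads of 16 nt or less have 1.26 or more exact matches expected by chance in the 2.71 Gb that the reads span, so the position of such a read need not be its origin. The cluster rule was tested on simulated libraries: it found 20 of 20 clusters planted at 200 RPM per window, 20 of 20 at 600 and 4 of 20 at 60, and 0 at places where none was planted. Planted reads were spread at random over each cluster on an even background, with stacks of copies only at single positions. The simulation therefore says nothing of regions with many copies on few left ends, where the limit of 20 left ends decides the call.

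Regions named in the text were chosen by a rule written before the data were examined: the 10 clusters with most reads per library, the 5 windows with the largest fold each way per pair of libraries, and the 5 left ends with most reads per library, of which the text gives examples. Other regions are said to have been chosen after their values were seen. Alternatives were counting each distinct interval once, other length ranges, cluster thresholds of 50 and 200 RPM, 5 kb windows, 5 distinct left ends, equal depth, left ends with at least 2 reads, and 50 RPM or 2-fold for windows. The planned first-base, ping-pong, phasing and strand measures, the annotation classes, the gene lists and the restriction to uniquely mapped reads were not computed, since each needs a strand, a sequence, read names or annotation of the build used. For the same reason left ends of intervals stood in for stranded 5′ ends.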

Results

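Reads from 2 MIWI2 immunoprecipitates (MEL erythroleukemia cells and splenocytes) were compared with the gel-purified small RNA band of adult testis, the tissue in which piRNAs are abundant. The design text states that the aim was to determine which piRNAs MIWI2 binds in erythropoietic cells. The MEL library held 823452 mapped reads on 181894 distinct intervals, the spleen library 692011 reads on 100908 and the testis library 1143785 reads on 304127. A distinct interval was therefore read 4.53 times on average in MEL, 6.86 times in spleen and 3.76 times in testis. In testis 50% of the reads fell on the 9857 most-read intervals, against 822 intervals in MEL and 329 in spleen. Each group had 1 library, so differences are given by size, without p-values, and the intervals cover counting error only.

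The first comparison was of read length, since piRNAs are longer than microRNAs. The testis RNA was cut from a gel near 29 nt, so its length shares were set in part by that selection and are no measure of the tissue against the immunoprecipitates. In testis, 93.64% of the reads (95% interval 93.6 to 93.69) were 24 to 32 nt long, with the most at 30 nt, which made up 31.53%. In MEL, 34.9% (34.8 to 35) were 24 to 32 nt long, with a broad maximum at 25 to 27 nt that held 23.58% of the reads. In spleen, 9.45% (9.38 to 9.52) were 24 to 32 nt long, and 59.86% (59.75 to 59.98) were 15 to 17 nt long. Reads of 29 to 31 nt, which made up 71.14% of testis, made up 3.04% (3.001 to 3.075) of MEL and 4.6% (4.55 to 4.65) of spleen. The microRNA range of 20 to 23 nt held 19.54% of the MEL reads, 4.67% of the spleen reads and 4.5% of the testis reads. Counted by distinct interval, the 24 to 32 nt share was 33.4% in MEL, 8.77% in spleen and 88.32% in testis. In the narrower range of 26 to 31 nt the share of reads was 20.56% in MEL, 7.0% in spleen and 85.46% in testis.

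**Figure D1:**
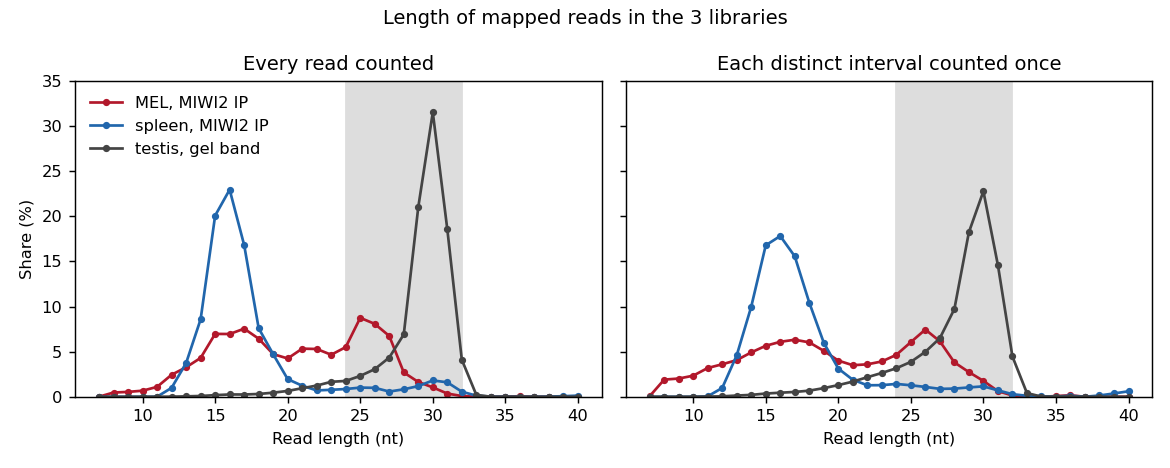
Share of each library (vertical axis, percent) at each read length (horizontal axis, nt), with every read counted at left and each distinct interval counted once at right; the grey band marks 24 to 32 nt. Testis peaks at 30 nt (31.53% of reads), MEL has a broad maximum at 25 to 27 nt and a second at 15 to 18 nt, and spleen peaks at 16 nt (22.96%).

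Testis reads came from few and large regions. By the cluster rule, 128 clusters covering 2.92 Mb held 93.29% (93.24 to 93.34) of the testis reads, where their length predicted 0.245%. The clusters were called on these same reads, so a testis share above that of their length follows from the rule. The 10 largest, each 50 to 90 kb wide, held 47.48% of the library, with 3.36% to 6.4% each. The largest lay on chromosome 17 from 27420001 to 27510000 and held 73194 reads, or 63992.8 RPM, on 8637 distinct left ends. The next were chromosome 9 from 67540001 to 67610000 (57788.8 RPM), chromosome 18 from 67190001 to 67250000 (55495.6 RPM) and chromosome 6 from 127730001 to 127800000 (52624.4 RPM). Reads of 29 to 32 nt were the most frequent in 126 of the 128 clusters. The left end with most reads in testis was 112646911 on chromosome 8, most often of 31 nt reads. It held 12905 reads, or 1.13% of the library (1.11 to 1.15).

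MEL cells had reads in the same regions as testis. All 128 testis clusters held at least 1 MEL read and 117 held at least 10, at a median of 125.1 RPM against 1543.6 in testis. Together they held 7.92% (7.87 to 7.98) of the MEL reads and 17.87% (17.73 to 18.02) of those of 24 to 32 nt, against 0.245% from their length. Over the chromosome 17 cluster MEL had 12492 reads on 3819 left ends, or 15170.3 RPM, 4.22-fold below testis. Over the 10 largest testis clusters the level in MEL was 4.22-fold to 23.93-fold below that in testis. In 1 of the 128 clusters MEL was above testis over all lengths: chromosome 1 from 172990001 to 173010000, named after its values were seen, had 5568.0 RPM in MEL (5408.0 to 5731.6) and 1304.4 in testis (1239.1 to 1372.4). There 57.88% of the MEL reads and 97.12% of the testis reads were 24 to 32 nt long. At 28 to 32 nt MEL had 404 reads and testis 1416, so the excess of MEL lay in shorter reads. Testis had 56 left ends in this cluster, against a median of 346 over its clusters. Across the 128 clusters log2 RPM in MEL and testis had a Pearson correlation of 0.92 and a Spearman correlation of 0.92; the clusters were chosen on the testis library and are not independent replicates. Over the 5236 windows with at least 10 RPM in either library the correlations were 0.04 and -0.11. That set was chosen by another rule, so these values are not comparable with those over the clusters.

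The MEL reads in testis clusters were shorter than the testis reads there. Their most frequent length was 26 nt, against 30 nt in testis, and the most frequent length was 24 to 28 nt in 108 of the 128 clusters in MEL. Of the 24 to 32 nt reads in the clusters, 19.95% (19.6 to 20.29) were 29 to 32 nt long in MEL and 80.54% (80.46 to 80.62) in testis. Outside the clusters 6.55% (6.45 to 6.65) of the MEL reads in this range were 29 to 32 nt long. Many of the left ends were the same in both libraries: 34.6% (34.18 to 35.02) of the distinct left ends of 24 to 32 nt MEL reads were left ends in testis, against 5.52% after random shifts.

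**Figure D2:**
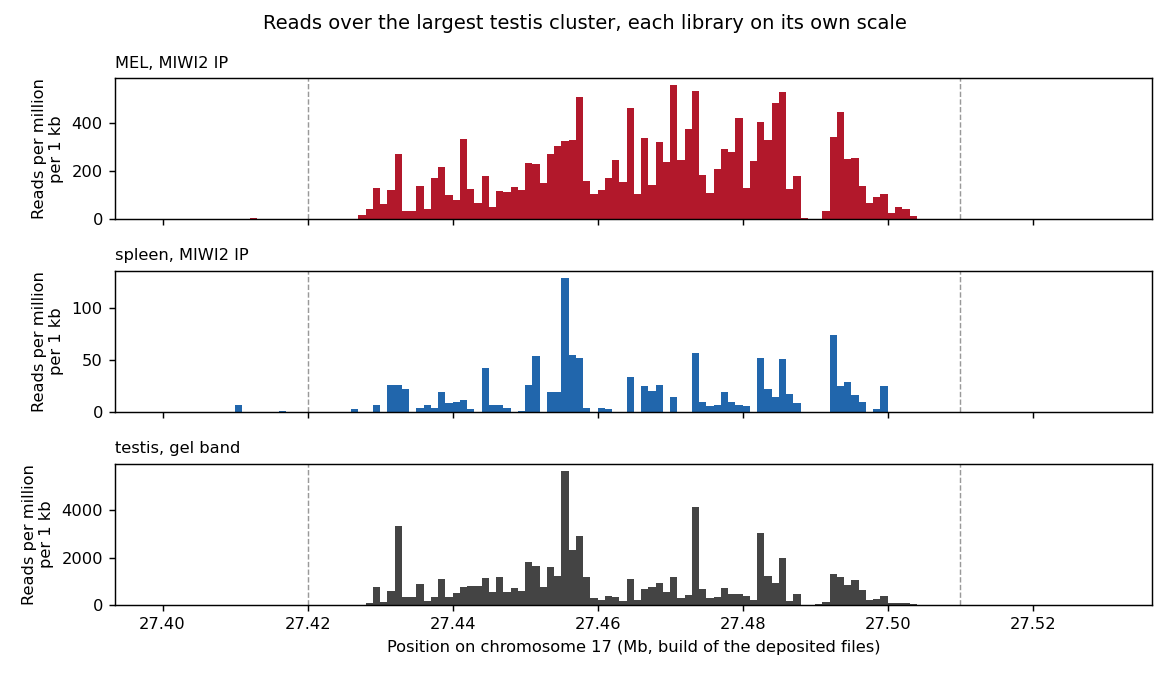
RPM in 1 kb bins (vertical axes, a separate scale for each library) over the testis cluster on chromosome 17 from 27420001 to 27510000, whose limits are the dashed lines, and 20 kb on either side (horizontal axis, Mb). Reads lie in 79 of the 90 bins of the cluster in MEL, 54 in spleen and 83 in testis; the flanks hold 20, 6 and 23 reads.

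Most MEL clusters lay elsewhere. The rule gave 166 clusters in MEL, covering 2.8 Mb and holding 33.96% (33.86 to 34.07) of its reads and 70.8% (70.64 to 70.97) of those of 24 to 32 nt. Of these, 64 overlapped a testis cluster and held 8.12% of the MEL reads, while 102 did not and held 25.85%. The 102 held fewer distinct ends, with a median of 34 distinct left ends against 139 in the 64, and a median of 18.23% of their reads on the most-read interval against 3.16%. The 2 largest were chromosome 6 from 47730001 to 47740000, with 25608.1 RPM in MEL, 1069.3 in spleen and 17.49 in testis, and chromosome 3 from 153570001 to 153580000, with 23554.5 in MEL, 187.9 in spleen and 36.72 in testis. A further example was chromosome 17 from 23670001 to 23690000, with 15894.1 RPM in MEL, 307.8 in spleen and 27.1 in testis. Chromosome 1 from 167570001 to 167580000 and chromosome 7 from 105960001 to 105970000 had near-equal values in MEL. They had 11137.3 and 11011.0 RPM, with 20.39% and 20.57% of the reads on the most-read interval. The treatment of reads with several matches is not given, so the 102 clusters need not be separate sources of reads. In each of the 10 largest MEL clusters the most frequent read length was 24 to 27 nt, and 2 of the 10 overlapped a testis cluster. Over all 166 clusters it was under 24 nt in 69, 24 to 28 nt in 94 and 29 to 32 nt in 3. Its median was 23 nt in the 102 clusters away from testis clusters and 26 nt in the 64. By the 4-fold rule 755 windows were higher in MEL than in testis, 534 of them with fewer than 3 testis reads, and 272 were higher in testis. Counting 26 to 31 nt reads alone, with RPM scaled to those reads, 263 windows were higher in MEL and 181 in testis. Among the windows with the largest fold over testis, chromosome 2 from 23010001 to 23020000 had 12059 MEL reads, 96.84% of them on the interval from 23017223 to 23017243, and 0 testis reads, which made it at least 5583.4-fold higher.

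Spleen reads in testis clusters were few and had the length of testis reads. The 128 clusters held 11446 spleen reads, or 1.65% (1.62 to 1.68) of the library, and 15.4% (15.12 to 15.67) of its 24 to 32 nt reads, against 0.245% from their length. Of the 128 clusters 119 held at least 1 spleen read and 83 at least 10, at a median of 27.46 RPM, and 0 were above testis. The chromosome 17 cluster had 805 spleen reads on 155 left ends, or 1163.3 RPM. Over the 10 largest testis clusters spleen was 49.92-fold to 76.39-fold below testis. The most frequent length of the spleen reads in the clusters was 30 nt, as in testis, and 77.47% (76.64 to 78.29) of those of 24 to 32 nt were 29 to 32 nt long. Outside the clusters 50.53% (50.11 to 50.95) of the spleen reads of 24 to 32 nt were 29 to 32 nt long, most often 31 nt, and over all lengths spleen reads there were most often 16 nt long. By distinct interval the 29 to 32 nt share was 22.86% outside the clusters and 77.11% inside. The single window on chromosome 7 from 118210001 to 118220000 held 22795 of the spleen reads of 24 to 32 nt, most often 31 nt long. Across the 128 clusters spleen and testis had a Pearson correlation of 0.92 and a Spearman correlation of 0.93 in log2 RPM. Over the 7410 windows with at least 10 RPM in either, a set chosen by another rule and not comparable, they were -0.19 and -0.15. Of the distinct left ends of 24 to 32 nt spleen reads, 28.64% (27.61 to 29.68) were left ends in testis, against 3.51% after random shifts.

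**Figure D3:**
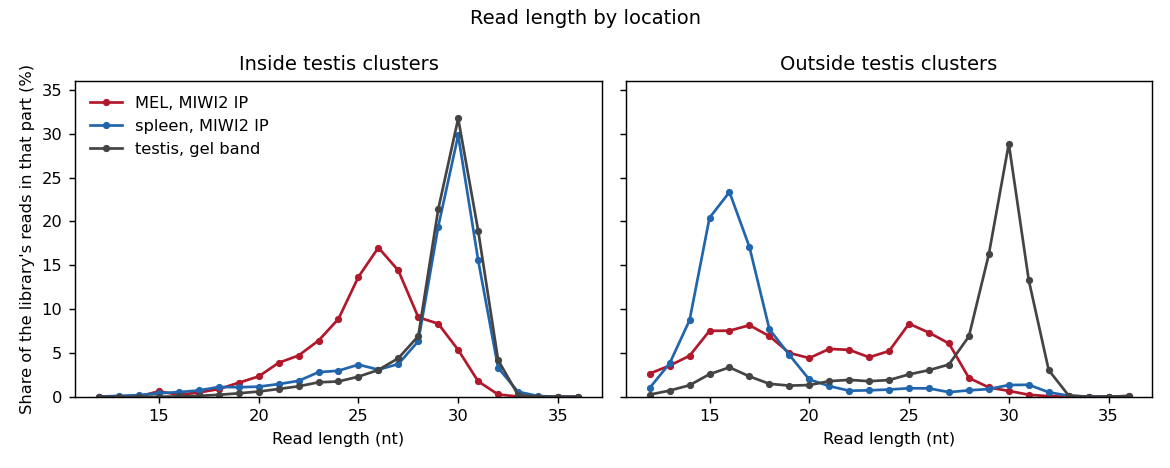
Share of a library's reads (vertical axis, percent) at each length from 12 to 36 nt (horizontal axis), for reads inside the 128 testis clusters at left and outside them at right. Inside the clusters the spleen and testis profiles both peak at 30 nt and the MEL profile peaks at 26 nt; outside, spleen peaks at 16 nt.

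**Figure D4:**
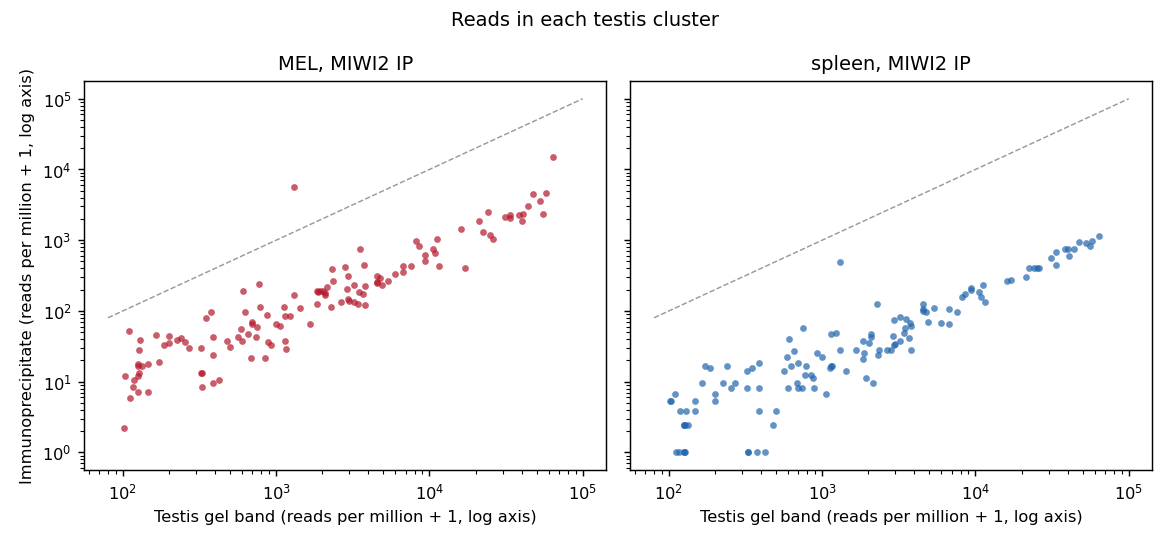
RPM (plus 1, log axes) in each of the 128 testis clusters, with testis on the horizontal axis and MEL (left) or spleen (right) on the vertical axis; the dashed line marks equal levels. In MEL 127 clusters lie below the line and 1, on chromosome 1, above it; in spleen all 128 lie below.

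Outside the testis clusters few positions held much of the piRNA-length reads of spleen, and the same was true of MEL. There 58.62% of the 24 to 32 nt reads of spleen, 70.4% of MEL and 9.78% of testis lay on intervals with 100 or more reads. Inside and outside the clusters together, 42 intervals held 50% of the 24 to 32 nt reads in spleen, 154 in MEL and 8339 in testis. The window on chromosome 7 from 118210001 to 118220000 alone held 22795 reads of 24 to 32 nt, 34.87% (34.51 to 35.24) of all spleen reads in that range, on 18 left ends and most often 31 nt long. It had 34070.3 RPM over all lengths in spleen, 81.36 in MEL and 5.25 in testis. The window on chromosome 8 from 112360001 to 112370000 held a further 9.57% (9.35 to 9.8) of the 24 to 32 nt reads, on 4 left ends. By the cluster rule spleen had 48 clusters holding 6.83% (6.77 to 6.89) of its reads, of which 20 overlapped a testis cluster. With at least 5 distinct left ends per window in place of 20, the clusters numbered 401 in spleen, 456 in MEL and 142 in testis. With 26 to 31 nt reads alone they numbered 18 in spleen, 111 in MEL and 130 in testis. The most-read left end, 98801761 on chromosome 12, was most often of 16 nt reads and held 27997 reads or 4.05% of the library (4.0 to 4.09), and the next, 52968644 on chromosome 13, most often of 17 nt reads, held 15027 reads or 2.17% (2.14 to 2.21). The one after it, 118219710 on chromosome 7, was most often of 30 nt reads and held 11176 reads or 1.62% (1.59 to 1.65). By the 4-fold rule 817 windows were higher in spleen than in testis, 642 of them with fewer than 3 testis reads, and 289 were higher in testis. With 26 to 31 nt reads alone, and RPM scaled to those reads, these were 407 and 171. Among those higher in testis, chromosome 9 from 67600001 to 67610000 had 1758.2 RPM in testis and 7.23 in spleen.

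The immunoprecipitates of MEL and spleen were then compared with each other. Of the spleen reads of 17 nt or less, 81.65% had a left end that MEL reads of that length also had, and 52.51% one that testis reads of that length had. Of the MEL reads of 17 nt or less, 57.82% had a left end found in spleen and 37.6% one found in testis. At 24 to 32 nt, 45.96% of the MEL reads had a left end found in spleen and 60.34% one found in testis, while 30.52% of the spleen reads had one found in MEL and 22.08% one found in testis. Counted by distinct left end, the shares at 17 nt or less were 13.78% (13.52 to 14.05) of MEL in spleen and 15.4% (15.11 to 15.69) of spleen in MEL, and at 24 to 32 nt 3.25% (3.1 to 3.41) and 21.74% (20.81 to 22.69). Windows with at least 100 RPM in both numbered 386 and held 34.03% of the MEL reads, 53.86% of the spleen reads and 63.23% of the testis reads. Of them 273 had under 10 RPM in testis and 77 had over 100. In 286 both immunoprecipitates had under 20 distinct left ends, and in 275 the most frequent spleen read was shorter than 20 nt. By the 4-fold rule 521 windows were higher in MEL and 470 in spleen. With 26 to 31 nt reads alone these were 120 and 339. There RPM was scaled to those reads, 169310 in MEL and 48466 in spleen. The limit of 100 RPM and the 3-read floor thus stood for other levels, and 120 and 339 are not comparable with 521 and 470. Over the 9157 windows with at least 10 RPM in either, the Pearson correlation was 0.02 and the Spearman correlation -0.08. Over the 128 testis clusters they were 0.91 and 0.91. The 2 sets were chosen by different rules, so these values do not show agreement in the clusters alone. Of the 386 windows with at least 100 RPM in both libraries, 253 differed by less than 4-fold. The window on chromosome 7 from 106630001 to 106640000 had 15255.3 RPM in MEL and 5.78 in spleen, with reads most often 24 nt long. In the other direction the window on chromosome 8 from 112360001 to 112370000 had 7211 reads in spleen, or 10420.4 RPM, and 1 read in MEL.

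By the cluster rule 20 regions were clusters in all 3 libraries, the chromosome 17 region and each of the other 9 largest testis clusters among them. They held 65.5% of the testis reads, 6.04% of the MEL reads and 1.18% of the spleen reads. Scaled to all reads, testis exceeded MEL there by a median of 14.72-fold and spleen by a median of 58.19-fold. These folds include the difference in read length between the libraries, since reads of 17 nt or less made up 34.3% of MEL, 73.19% of spleen and 0.856% of testis. Among 24 to 32 nt reads the 128 testis clusters held 17.87% in MEL, 15.4% in spleen and 94.3% in testis. By distinct interval of that length they held 47.72%, 24.98% and 82.84%. The cluster on chromosome 1 from 172990001 to 173010000 was the exception in both: testis was 0.234-fold of MEL and 2.67-fold of spleen, while the other 19 ranged from 4.22-fold to 25.37-fold and from 36.93-fold to 76.39-fold.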

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

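Settings chosen after seeing the data were leaving out the 5 most-read windows, 24 to 32 nt or at least 18 nt reads in the same clusters, and right ends, both ends or 24 to 32 nt reads for shared ends. The alternatives changed levels but left the order of the libraries (testis above MEL above spleen) in the 24 to 32 nt share and in the share of reads in testis clusters under each setting run. Of 84 recomputed values, 56 moved by more than counting error or 1.5 times and 28 did not. The 24 to 32 nt share in MEL, spleen and testis was 33.4%, 8.77% and 88.32% by distinct interval, 20.56%, 7.0% and 85.46% for the range 26 to 31 nt, and 32.62%, 7.25% and 93.49% without the 5 most-read windows of each. The share in testis clusters was, in the same order, 20.31%, 2.6% and 81.55% by distinct interval, 21.26%, 18.36% and 94.32% for 26 to 31 nt reads with clusters called on these, 17.87%, 15.4% and 94.3% for 24 to 32 nt reads, 11.89%, 6.05% and 93.95% for reads of at least 18 nt, and 7.56%, 1.61% and 92.84% with 5 kb windows. At 50 RPM it was 8.05% in MEL and 93.9% in testis, and at 200 it was 7.83% and 92.69%. The number of clusters held within 1.5 times, except for 18 in spleen with 26 to 31 nt reads and 456 in MEL and 401 in spleen with at least 5 left ends, where testis had 142; at equal depth it was 157, 48 and 124. The distinct left ends of MEL also in testis, of spleen also in testis and of MEL also in spleen were 39.1%, 37.66% and 3.55% for 26 to 31 nt reads, 34.6%, 28.64% and 3.25% for 24 to 32 nt reads, 13.08%, 3.62% and 9.52% at equal depth, 20.6%, 6.25% and 17.43% for left ends with at least 2 reads, and 9.93%, 3.15% and 7.26% with both ends the same, where all reads gave 14.22%, 4.15% and 8.98%; right ends gave 8.77% for MEL in spleen. At 50 RPM the windows higher in MEL and in spleen numbered 794 and 869 against each other and 1201 and 1440 against testis. With 26 to 31 nt reads 120 were higher in MEL than in spleen, 263 in MEL and 181 in testis, and 407 in spleen and 171 in testis. RPM was scaled to those reads there, so part of the change from all reads can come from the scaling. The cause of these differences was not tested. Spleen had 65363 reads of 24 to 32 nt, which may limit what can be seen of its clusters. The other libraries were not thinned to that number, so this was not tested. Not run were the planned restriction to reads with a single line and the alternatives for the first base, annotation classes, ping-pong, phasing, strand asymmetry and gene lists.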

Other observations

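Chosen only after the result was seen were the tests of the MEL read length, of the exact ends of MEL reads and of distinct MEL and spleen intervals, of single clusters, of chance placement of MEL and of spleen reads, and, for the correlations of all cluster reads with testis, the limit used to read them.

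The chromosomes contributed unequally to testis and more evenly to the immunoprecipitates. The X chromosome held 0.173% (0.165 to 0.181) of the testis reads, against 2.76% (2.73 to 2.8) in MEL and 2.67% (2.64 to 2.71) in spleen, and chromosomes 16 and 19 held 0.202% and 0.313% of the testis reads, against 3.65% and 1.48% in MEL and 2.39% and 2.34% in spleen. Chromosome 7 held 11.61% of the testis reads, chromosome 9 held 10.6% and chromosome 5 held 9.69%. The mitochondrial genome held 1822 reads in MEL (0.221%), 2372 in spleen (0.343%) and 9 in testis. These are values from 1 library each.

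Several regions outside the testis clusters had reads in spleen at many positions. Chromosome 11 from 101460001 to 101520000 had 5722.5 RPM on 242 left ends in spleen, 573.2 in MEL and 94.42 in testis. Chromosome 1 from 72270001 to 72310000 had 1966.7 RPM in spleen on 159 left ends, 180.9 in MEL and 2.62 in testis. Chromosome 12 from 55790001 to 55840000 had 1554.9 on 270 left ends, against 167.6 and 5.25. Chromosome 17 from 39980001 to 39990000 was at similar levels in both immunoprecipitates, with 2574.5 RPM on 454 left ends in MEL and 2362.7 on 41 left ends in spleen, and had 14.86 in testis.

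The spleen reads in testis clusters may in large part be carried over from testis material rather than bound by MIWI2 in spleen: of the 8522 of 28 to 32 nt, 88.47% (87.77 to 89.14) had both ends at those of a testis read, against 88.69% for the testis library's own reads, each left out in turn, and so did 86.37% (84.73 to 87.89) of their distinct intervals, against 84.72% to 88.87% in 100 draws from testis. Against it, the correlation with testis over the 128 clusters was 0.9203 by all reads and 0.9087 by 28 to 32 nt reads, where the lowest of 100 draws gave 0.9725 and 0.9655. The correlation by all reads met its first limit, 0.9 of the draws' mean (ratio 0.9387), and was set against the lowest draw only after it was seen. That by 28 to 32 nt reads missed the limit set before it. Only after these came out low was it found that the 8522 reads lay on 1878 intervals, where as many testis reads lay on 6355.5 on average; both correlations were then set aside because the draws lack such copies, and one of distinct intervals was added, which gave 0.9318, inside the 0.9267 to 0.9646 of draws. Cluster by cluster, distinct intervals lay outside the range of 100 draws in 4 of 128, as many as in the most extreme draw, but carry-over alone is argued against for the cluster on chromosome 1 from 172990001 to 173010000, which had 24 where no draw had more than 6. Open for the others are carry-over of this or another testis library or RNA, and piRNAs of spleen with lengths and proportions near those of testis, since no input or control immunoprecipitate was analysed here.

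The MEL reads in testis clusters are unlikely to be reads of the sequenced testis library alone, since 19.95% of those of 24 to 32 nt were 29 to 32 nt long, against 80.54% in testis, and since 78.81% (78.17 to 79.44) of the 16166 of 28 to 32 nt, or 72.01% (71.14 to 72.87) of their distinct intervals, had both ends at those of a testis read, where the lowest of 100 draws from testis gave 88.13% and 82.4%; distinct intervals lay outside the draws' range in 16 of the 128 clusters, against at most 8 in a draw. Their correlation with testis over the clusters, 0.9221, met its first limit (ratio 0.9263 to the draws' mean), but lay below the lowest of 100 draws, 0.9894, a comparison made after the value was seen. Chance placement of short reads is argued against by the 0.3335% of MEL reads of 17 nt or less that lay in the clusters, where 17.87% of those of 24 to 32 nt did. For 28 to 32 nt reads the correlations, 0.9599 by reads and 0.9633 by distinct intervals, lay less than 0.02 below the lowest draws (0.976 and 0.9696), which was the margin set beforehand and decides nothing. Carry-over as a part of the reads, testis RNA that entered before size selection, loss of bases from the ends, and piRNAs of MEL cells stay open and were not tested.

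The short reads of spleen may be fragments of RNAs that are also in the other libraries. Of the 2601 left ends with at least 10 reads of 15 to 17 nt, 77.01% (75.34 to 78.61) were left ends in MEL, against 0.0254% after random shifts, and 15.53% were left ends in testis. These are the most-read ends. Of all 59404 distinct left ends of spleen reads of 17 nt or less, 15.4% were found in MEL and 1.63% in testis among reads of that length. By reads, 81.65% of the spleen reads of 17 nt or less lay at left ends of MEL and 52.51% at those of testis. Testis had 5025 such ends. The sharing was thus also seen with a library that was no immunoprecipitate. Whether the short testis reads came from testis RNA or were carried over from the other libraries was not tested. Of the 15 to 17 nt reads 64.89% (64.74 to 65.03) lay on intervals with 100 or more reads, which does not decide whether they were placed by chance, since copies of a sequence stack wherever it is placed. Degraded cellular RNA, RNA held by beads or antibody, and RNA from reagents were not tested, and at these lengths a mapped position need not be the origin.

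A hypothesis from the interval ends is that many testis clusters are read mainly from 1 strand, although the deposited positions carry no strand. If 5′ ends are more fixed than 3′ ends, such a cluster would have more distinct ends on the same side throughout. Over the 102 clusters with at least 50 distinct intervals in even and in odd 1 kb bins, the log2 ratio of distinct right to distinct left ends of 24 to 32 nt reads ran from -0.67 to 0.72. Its values in even and in odd bins had a Pearson correlation of 0.9728 and a Spearman correlation of 0.89, with the same sign in 99 of 102. This is consistent with a strand preference that holds along a cluster, 45 clusters having more right ends and 57 more left ends, but another property of a cluster that holds along its length could give the same, and stranded alignments would be needed. The largest cluster, on chromosome 17 from 27420001 to 27510000, had 7934 right and 7940 left ends, so it showed no such side preference. Other large clusters differed. The log2 ratio was 0.02 on chromosome 5 from 113750001 to 113800000 and -0.56 on chromosome 5 from 150590001 to 150640000. On chromosome 2 from 92380001 to 92450000 it was 0.54.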
